A study of Mus musculus with 8 samples.

How the data were processed

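The series comprised 8 liver samples of male mice, 2 for each combination of a genotype label (Fxr+/+ or Fxr-/-) and a treatment (vehicle or GW4064). Per the labels' protocols, RNA was extracted with Trizol, cleaned on columns with DNase treatment, and converted to biotin-labelled cRNA for Illumina bead arrays, and each sample was a pool of 3 to 4 animals. The labels do not say whether the pools of a group were processed separately in other ways. P-values of genes therefore measure the spread between these pools.

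The deposited table holds 1 column per array and 25697 probes. In 7 columns the authors deposited an intensity per probe on a linear scale. These values were already background-subtracted, since between 31.5% and 31.6% of each column was below 0 with a minimum of -39.5, and already quantile normalized, since the sorted values of the 7 columns differed by at most 0.5. The software behind these steps is not given in the sources used here, and the file carried no detection p-values. The deposited column of Fxr-/- vehicle replicate 2 held other values, whose unit is not known. All of its values were whole numbers (100%, against 10.1% to 10.2% in the others), its median was 39, its variance was 1.43 times its mean, and its highest Spearman correlation with another array was 0.0559. It was left out of every fit, which differs from the plan made before the data were examined, where all 8 arrays entered. As a result the Fxr-/- vehicle group held 1 array.

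Probes were named through the platform's annotation, with symbols checked by Entrez identifier against RefSeq genes of assembly GRCm38.p6. Of the probes, 23978 had 1 symbol, 0 had several and 1719 had none, and 16 of those with a symbol had no match. No symbol changed. The build used to design the array is not given in the sources used here, so no coordinates are printed.

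Signals were converted as log2(max(signal, 0) + 16), with no further normalization. Fold changes are on this scale, which understates the change of dim genes. A probe was kept when it exceeded the median (percentile 50) of its array on at least 2 arrays, which left 14041 probes. Of 16593 genes on the array, 9766 were tested, each through its kept probe with the highest mean. For the named genes results/ also held the other kept probes, and a disagreement in sign is stated beside the gene. A probe whose signal was under 39.5, the size of the most negative value, on every array of a group was treated as within the range of the background there. Its ratio to the other group is then given as "at least N-fold", with signals under 39.5 set to that size, and no fold is given where both groups were within that range.

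All 7 arrays entered 1 cell-means fit in limma 3.58.1 (R 4.3.3) with 3 residual degrees of freedom, 4.56 prior degrees of freedom and a prior SD of 0.228 on the log2 scale. The comparisons were GW4064 against vehicle within each genotype label, the difference between these effects, and Fxr-/- against Fxr+/+ under each treatment, the last of these for counts and lists only. Tests were two-sided with Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. The 28 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. P-values for lists were adjusted over the 28 lists of a comparison. Figures were drawn with matplotlib 3.10.9.

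The named genes followed a rule fixed before the data were examined. It took Nr1h4, 10 fixed genes of bile acid and drug metabolism, the 8 largest rises and 8 largest falls past the threshold whose groups did not overlap, and up to 3 members of each list with the smallest p among those past the threshold. Where under 5 genes passed in a direction, the 5 with the smallest unadjusted p were named as not having passed.

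The fit was tested on simulated data, with values drawn from the real means and spread of the 9766 genes and 200 genes changed in each of 10 rounds. For GW4064 against vehicle in Fxr+/+, 39.7% of genes changed 2-fold and 99.7% of those changed 4-fold were recovered. For GW4064 against vehicle in Fxr-/- the shares were 0.65% and 97.7%, and for Fxr-/- against Fxr+/+ under vehicle 1.35% and 97.0%. For 4-fold changes the false calls were between 6.22% and 6.97% of the calls, and for 2-fold changes they reached 18.9% for GW4064 against vehicle in Fxr-/-. The recovered shares hold for 200 changed genes with noise drawn independently for each gene. With fewer changed genes the adjusted threshold is harder to pass. In the real Fxr+/+ comparison Slc51b, with a log2 change of 2.81, did not pass. A shift of -0.50 in 1 list of 18 genes was found by camera in 10 of 10 rounds, with 0 calls in 270 tests of lists without a shift, for genes simulated as independent.

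The alternatives were an added quantile normalization, median centring, offsets of 1 and 100, no filter and a stricter filter, all probes and the mean of a gene's probes, limma with trend and robust settings, array weights, fits of only the groups compared, the replicate number as a block, an added fold threshold, and each array left out. The groups share the replicate numbers 1 and 2, and no label says that these pair samples.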

Results

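Hepatic transcript levels were measured in male mice on an Illumina bead array of 25697 probes. Mice labelled Fxr+/+ or Fxr-/- had been gavaged with vehicle or with GW4064 at 30 mg/kg, 2 times a day for 7 days. GW4064 is a synthetic agonist of the farnesoid X receptor (FXR), the nuclear receptor for bile acids, which is encoded by Nr1h4. Each array was hybridised with liver RNA pooled from 3 to 4 animals, and 2 arrays were deposited for each of the 4 groups. Of the 8 columns, 7 held background-subtracted signals. The column of Fxr-/- vehicle replicate 2 held only whole numbers between 14 and 139, with a Spearman correlation of at most 0.0559 with any other array, and was not used as expression. The Fxr-/- vehicle group therefore rested on 1 array, which was assumed to vary like the other groups. The number of arrays limits the precision throughout, and each p-value of a gene measures the spread between pools. Camera p-values at the preset correlation set a list's members against the other genes, and do not measure that spread.

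The genotype label separated the arrays along the first axis of variation. Principal component 1 held 64.2% of the variance over the 9766 genes tested, and it placed the 4 Fxr+/+ arrays between -31.6 and -28.2 and the 3 arrays labelled Fxr-/- between 35.9 and 46.7. Components 2 and 3 held 12.8% and 9.42%. Spearman correlations over all probes lay between 0.965 and 0.969 for arrays of the same group, between 0.945 and 0.969 for arrays of the same genotype label under different treatments, and between 0.935 and 0.956 for arrays of different genotype labels.

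The targeted gene was read first. Nr1h4 was not lost in the arrays labelled Fxr-/-. Its signal was 4185 ± 320 (SD, n = 2) in Fxr+/+ vehicle and 3405 ± 110 (SD, n = 2) in Fxr+/+ GW4064 arrays, against 3272 in the vehicle array and 1950 ± 139 (SD, n = 2) in the GW4064 arrays labelled Fxr-/-. Under vehicle the log2 difference between the labels was -0.35 (SE 0.228, limma adjusted p = 0.389). Under GW4064 both arrays labelled Fxr-/- lay lower, at 2048 and 1852 against 3328 and 3483 in Fxr+/+. It is not known here whether the probe lies inside the deleted part of the gene. A probe outside that part would not check the label. The genotype is therefore given as labelled throughout, and every direction between genotypes rests on these labels.

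The first comparison asked which liver genes GW4064 changed in Fxr+/+ mice. A bile acid gene fell and a cytochrome P450 gene rose. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from a signal of 6039 ± 1562 to 993 ± 12.3 (SD, n = 2 each; log2 change -2.56, SE 0.245, adjusted p = 0.0447). Cyp2b13, a P450 of the female-predominant liver programme whose probe may cross-hybridise with its paralogs Cyp2b9 and Cyp2b10, rose from 46.2 ± 2.40 to 436 ± 94.5 (SD, n = 2 each; log2 change 2.84, SE 0.216, adjusted p = 0.017). These were the only genes past the threshold in limma, 1 higher and 1 lower. At an unadjusted p under 0.05 there were 493 genes, against 488 expected by chance. Both calls were lost when any single Fxr+/+ array or either Fxr-/- GW4064 array was left out, with adjusted p between 0.051 and 0.269 for Cyp2b13 and between 0.0964 and 0.491 for Cyp7a1 in those fits. Both were also lost when only the 4 Fxr+/+ arrays were fitted (adjusted p = 0.102 and 0.148).

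Other FXR-regulated genes had sizeable values without passing. Slc51b, a subunit of the basolateral bile acid exporter, had signals of 52.3 ± 2.05 under vehicle and 507 ± 300 under GW4064 (SD, n = 2 each; log2 change 2.81, SE 0.367, adjusted p = 0.133). The log2 change of Cyp8b1, the sterol 12-alpha-hydroxylase that sets the share of cholic acid, was -1.57 (SE 0.363, adjusted p = 0.622), with signals of 19084 ± 1774 and 6396 ± 125 (SD, n = 2 each). Abcb11, the canalicular bile salt export pump, had a log2 change of 0.57 (SE 0.221, adjusted p = 0.972) and Abcb4, the phospholipid transporter, 0.03 (SE 0.201). Slc10a1 had a value of -0.36 (SE 0.281), Cyp3a11 0.42 (SE 0.321), Cyp2b10 1.11 (SE 0.229, adjusted p = 0.537) and Nr1h4 -0.29 (SE 0.186), and none passed. The probe of Nr0b2, which encodes the repressor SHP, had signals between -25.3 and -5.1 on all 7 arrays and was not tested. Slc51a stayed within the range of the background in both groups, so no fold is given for it.

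The genes next in line by unadjusted p also did not pass. Among higher values these were Gstm3, a glutathione S-transferase (at least 3.60-fold, adjusted p = 0.104), Tceal5 (at least 3.25-fold, adjusted p = 0.104) and Amn, the amnionless subunit of an intestinal and renal receptor (log2 change 1.64, SE 0.214, adjusted p = 0.133). Among lower values they were Csad, a taurine synthesis enzyme (-1.31, SE 0.223, adjusted p = 0.294), Fbxo21 (-0.996, SE 0.201, adjusted p = 0.537), Itpka (at least 1.55-fold, adjusted p = 0.43) and Brwd3 (at least 1.08-fold, adjusted p = 0.43). The bounds set a signal within the background range, whose size is 39.5, to that size.

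Of the 28 gene lists, 18 passed camera with a preset correlation of 0.01 in Fxr+/+ mice, 9 upward and 9 downward. None passed with an estimated correlation, and none passed fry. Each list's adjusted p with an estimated correlation is given after its preset one. Lists of cholesterol synthesis, bile acid synthesis, fatty acid oxidation and gluconeogenesis fell, and none of these had more than 1 member past the threshold over all genes. Cholesterol synthesis and uptake had 18 of 18 members below 0 (median log2 change -0.38, adjusted p = 1.07e-08; 0.193 with an estimated correlation), with 0 members past the threshold over all genes and 1 adjusted over the list alone. Bile acid synthesis and conjugation had a median of -0.31 with 10 of 17 members below 0 (adjusted p = 0.0386; 0.408 with an estimated correlation), with 1 member lower over all genes and 3 adjusted over the list alone. Fatty acid oxidation and PPAR-alpha targets had a median of -0.19 over 22 members (adjusted p = 0.00306; 0.193 with an estimated correlation), and gluconeogenesis -0.22 over 15 (adjusted p = 0.00243; 0.193 with an estimated correlation).

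The xenobiotic and antioxidant lists rose in Fxr+/+ mice. NRF2 and glutathione genes had a median of 0.36 with 18 of 22 members above 0 (adjusted p = 1.92e-09; 0.193 with an estimated correlation), of which 0 passed over all genes and 8 adjusted over the list alone. CAR and PXR targets had a median of 0.31 with 18 of 24 above 0 (adjusted p = 7.15e-08; 0.271 with an estimated correlation), with 1 member past the threshold over all genes, Cyp2b13, and 5 adjusted over the list alone. FXR target genes had a median of 0.14 with 17 of 25 above 0 (adjusted p = 0.00353; 0.193 with an estimated correlation), and 1 member, Slc51b, passed adjusted over the list alone. Bile acid and canalicular transport had a median of 0.06 over 15 members (adjusted p = 0.0425; 0.408 with an estimated correlation).

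Lists of liver sex programmes, zones and other cell types moved in the same arrays. Some lists share members, so their calls are not separate findings. Cyp7a1 is in the bile acid synthesis and the pericentral list, and Cyp2b13 in the CAR and PXR and the female-predominant list. Male-predominant genes fell, with 14 of 14 members below 0 (median -0.75, adjusted p = 6.75e-10; 0.193 with an estimated correlation) and 7 lower adjusted over the list alone, while female-predominant genes had a median of 0.44 over 10 members (adjusted p = 0.000513; 0.201 with an estimated correlation). Pericentral genes had a median of -0.36 (adjusted p = 1.43e-05; 0.309 with an estimated correlation). Cell cycle genes had a median of 0.39 with 21 of 22 members above 0 (adjusted p = 1.29e-08; 0.196 with an estimated correlation), and acute phase genes 0.16 over 27 (adjusted p = 0.000744; 0.193 with an estimated correlation). Complement and coagulation had a median of -0.17 over 26 members (adjusted p = 0.000377; 0.387 with an estimated correlation) and ER stress -0.14 over 20 (adjusted p = 0.0408; 0.368 with an estimated correlation). Lymphocyte markers had a median of 0.40 (adjusted p = 0.000787; 0.408 with an estimated correlation), neutrophil markers 0.41 (adjusted p = 0.00246; 0.494 with an estimated correlation), and stellate cell and matrix markers -0.22 (adjusted p = 0.018; 0.587 with an estimated correlation). The other 10 lists did not pass, with adjusted p between 0.0593 and 0.766. These were fatty acid and triglyceride synthesis, lipoproteins, amino acid and one-carbon metabolism, the circadian clock, periportal genes, and the markers of macrophages, endothelial cells, bile duct cells, red blood cells and pancreatic acinar cells.

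Of these 18 list calls, 9 were kept whichever array was left out. Without Fxr+/+ vehicle replicate 1 the calls of bile acid synthesis (adjusted p = 0.414), fatty acid oxidation (0.285, median -0.11), gluconeogenesis (0.285, median -0.14), ER stress (0.834) and stellate markers (0.59) were lost. Without Fxr+/+ vehicle replicate 2 those of FXR targets (0.0852), bile acid transport (0.41, median 0.01), lymphocyte (0.266, median 0.18) and neutrophil markers (0.475, with the median turning to -0.07) were lost. Leaving out Fxr+/+ GW4064 replicate 1 ended the calls of bile acid synthesis (0.0667), bile acid transport (0.0521, median 0.03), ER stress (0.237, median -0.07) and stellate markers (0.748, with the median turning to 0.05). Leaving out Fxr+/+ GW4064 replicate 2 ended those of FXR targets (0.0817, median 0.03), bile acid synthesis (0.0757), bile acid transport (0.0644, median 0.11), gluconeogenesis (0.0644) and lymphocyte markers (0.617, median 0.05). Without either Fxr-/- GW4064 array, bile acid transport (0.0502) and ER stress (0.051) missed the threshold.

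Where a call was kept, some medians still moved by more than 1.5 times. Without Fxr+/+ vehicle replicate 1 they were 0.21 for bile acid transport, 0.64 for the cell cycle and 0.83 for neutrophil markers. Without vehicle replicate 2 they were -0.16 for bile acid synthesis, -0.285 for fatty acid oxidation, -0.09 for complement, 0.21 for the cell cycle and -0.255 for ER stress. Without GW4064 replicate 1 they were 0.24 for FXR targets, -0.39 for gluconeogenesis, 0.24 for acute phase genes, -0.11 for complement, 0.27 for female-predominant genes and 0.64 for lymphocyte markers, and without GW4064 replicate 2 -1.16 for male-predominant genes and -0.37 for stellate markers.

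**Figure D1:**
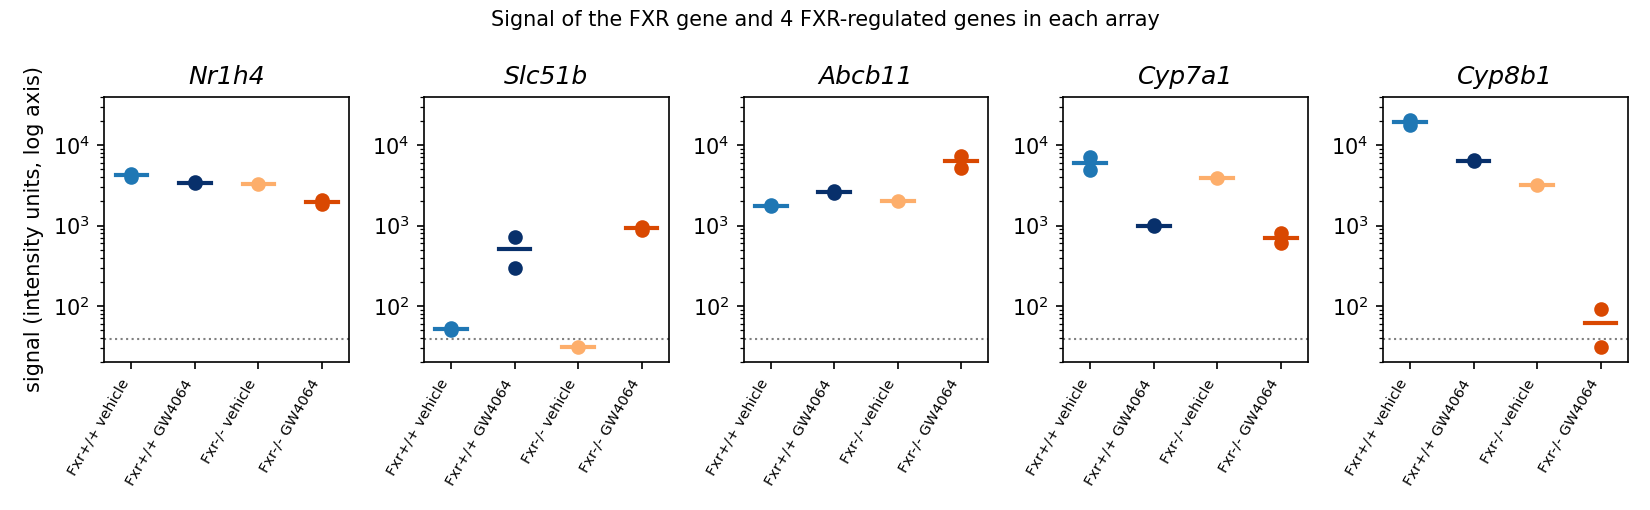
Signal of the FXR gene (Nr1h4) and of 4 FXR-regulated genes in each of the 7 usable arrays, by group (x axis) on a log axis of intensity (y axis). Points are arrays, bars are group means and the dotted line marks the size of the background range, 39.5. Nr1h4 lies between 1852 and 4411 on every array, and Cyp7a1 is lower under GW4064 than under vehicle within each genotype label.

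The second comparison asked whether GW4064 changed genes in mice labelled Fxr-/-, where an effect through the receptor would be missing. In these arrays 7 genes passed, 5 higher and 2 lower, and 949 genes had an unadjusted p under 0.05 against 488 expected by chance. Slc51b rose from a signal of 30.8 on the vehicle array, within the background range, to 919 ± 54.0 (SD, n = 2), at least 23.2-fold (adjusted p = 0.0456). Cyp8b1 fell from 3164 to 61.5 ± 43.7 (SD, n = 2; log2 change -5.48, SE 0.445, adjusted p = 0.0138), and 1 of its 2 GW4064 arrays lay within the background range. The antioxidant genes Gstm3 (at least 4.62-fold, adjusted p = 0.0138) and Gpx2, the gastrointestinal glutathione peroxidase (at least 2.75-fold, adjusted p = 0.0456), rose, as did 1 probe of Synm, an intermediate filament protein (at least 7.34-fold, adjusted p = 0.0456), and Etv4, an ETS transcription factor (at least 2.39-fold, adjusted p = 0.0456). Of the 3 kept probes of Synm the lowest had a log2 change of 0.02, and with the mean of the probes its call was lost (adjusted p = 0.129). Mfap2, a microfibril protein, fell at least 2.54-fold (adjusted p = 0.0488).

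Other named genes did not pass in arrays labelled Fxr-/-. Cyp7a1 had signals of 3846 under vehicle and 709 ± 136 under GW4064 (SD, n = 2; log2 change -2.43, SE 0.30, adjusted p = 0.0599). Abcb11 had 2003 and 6239 ± 1526 (SD, n = 2; log2 change 1.61, SE 0.271, adjusted p = 0.137). Socs2, a suppressor of growth hormone signalling, had a log2 change of -1.87 (SE 0.266, adjusted p = 0.117), and C1qtnf2 was at least 1.20-fold lower (adjusted p = 0.134); neither passed. Values were -0.93 (SE 0.345) for Slc10a1, 0.56 (SE 0.393) for Cyp3a11, 0.29 (SE 0.281) for Cyp2b10, -0.74 (SE 0.228) for Nr1h4 and -3.47e-05 (SE 0.246) for Abcb4, and none passed. Slc51a was within the background range in both groups.

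These calls rested on 1 vehicle array, which has replicate number 1, and on the spread of the other groups. That array could not be left out, since its group would then be empty, so each fit below left out 1 of the other 6. The call of Cyp8b1 was kept in all 6 fits that left out 1 array (highest adjusted p = 0.045). That of Gstm3 was lost without Fxr-/- GW4064 replicate 1 (0.098) or 2 (0.176), and that of Slc51b without either of these (0.127 and 0.245) and without either Fxr+/+ vehicle array (0.0782). The calls of Gpx2, Synm, Etv4 and Mfap2 were lost whichever array was left out, with adjusted p up to 0.245. With only the 3 arrays labelled Fxr-/- no gene passed. A block on the replicate number ended the calls of Slc51b, Etv4, Mfap2 and Synm.

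Of the 28 lists, 8 passed in arrays labelled Fxr-/-, 3 upward and 5 downward. None passed with an estimated correlation, whose adjusted p follows each, and none passed fry. FXR target genes rose (median 0.29, 14 of 25 members above 0, adjusted p = 0.000568; 0.355 with an estimated correlation), with 1 member higher over all genes and 7 adjusted over the list alone. NRF2 and glutathione genes rose (median 0.48, 15 of 22 above 0, adjusted p = 4.79e-06; 0.355 with an estimated correlation), with 2 members higher over all genes, Gstm3 and Gpx2, and 8 adjusted over the list alone. Acute phase genes had a median of 0.20 over 27 members (adjusted p = 0.0365; 0.487 with an estimated correlation). Cholesterol synthesis and uptake fell (median -0.35, 14 of 18 below 0, adjusted p = 0.00171; 0.487 with an estimated correlation), as did bile acid synthesis and conjugation (median -0.27, 12 of 17 below 0, adjusted p = 0.0329; 0.544 with an estimated correlation), where Cyp8b1 passed over all genes and 2 members adjusted over the list alone. Pericentral genes had a median of -0.54 (adjusted p = 0.000267; 0.544 with an estimated correlation).

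Cell type markers moved with the treatment in these arrays too. Endothelial markers fell, with 15 of 15 members below 0 (median -0.60, adjusted p = 8.04e-06; 0.487 with an estimated correlation), and so did macrophage and Kupffer cell markers (median -0.39, adjusted p = 0.0363; 0.666 with an estimated correlation). The remaining 20 lists did not pass (adjusted p between 0.0632 and 0.893). They were bile acid transport, fatty acid and triglyceride synthesis, fatty acid oxidation, lipoproteins, gluconeogenesis, CAR and PXR targets, complement, amino acid metabolism, the cell cycle, ER stress, the clock, both sex-biased lists, periportal genes and the markers of neutrophils, lymphocytes, stellate cells, bile duct cells, red blood cells and acinar cells. Without Fxr-/- GW4064 replicate 2 the calls of bile acid synthesis (0.414, median -0.02), macrophage markers (0.275, median -0.20) and pericentral genes (0.213, median -0.16) were lost, and the endothelial median was -0.39. Without replicate 1 the call of acute phase genes was lost (0.202), and the medians of FXR targets, bile acid synthesis and pericentral genes were 0.12, -0.57 and -0.89.

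The difference of the GW4064 effect between the genotype labels was tested directly, as the effect in Fxr+/+ minus that in Fxr-/-. No gene passed in limma (0 higher, 0 lower, smallest adjusted p = 0.305), and 600 genes had an unadjusted p under 0.05 against 488 expected by chance. The 5 genes with the smallest p above 0 were Cyp2b9 (3.94, SE 0.524), Cyp2b13 (2.97, SE 0.341), Cyp8b1 (3.91, SE 0.574), Tmprss4 and Car9. Below 0 they were Synm, Etv4, Hcn2, Cdkl1 and Mecom. None of these passed (adjusted p between 0.305 and 0.331), and all but Cyp2b9, Cyp2b13 and Cyp8b1 lay within the background range in at least 1 group, so no size is given for them. For the fixed bile acid genes the differences were -0.13 (SE 0.387) for Cyp7a1 and -1.04 (SE 0.35) for Abcb11. Slc51b (adjusted p = 0.757) and Slc51a (adjusted p = 0.996) had groups within the background range, so no size is given for them. They were 0.03 (SE 0.317) for Abcb4, 0.57 (SE 0.445) for Slc10a1, -0.14 (SE 0.507) for Cyp3a11, 0.83 (SE 0.362) for Cyp2b10 and 0.45 (SE 0.294) for Nr1h4, and none passed.

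Genes changed by GW4064 in Fxr+/+ mice were then read in the arrays labelled Fxr-/-, which share no array with them. Of the 2 called genes, Cyp7a1 had the same sign there and Cyp2b13 did not (-0.12). Of the 493 genes with an unadjusted p under 0.05 in Fxr+/+, 328 (66.5%) had the same sign in Fxr-/-, against 52.5% of all genes. There were 68 genes higher and 33 lower at that p in both, where independent lists would give 13.7 and 9.98. The same estimate of each gene's spread enters both effects, which can raise this overlap. Across all genes, which are not independent replicates, Pearson's r between the effects was 0.169 and Spearman's rho 0.094.

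Of the 28 lists, 11 passed camera for this difference, 7 upward and 4 downward, and none with an estimated correlation (adjusted p between 0.489 and 0.585) or with fry. Those higher were CAR and PXR targets, the cell cycle, female-predominant genes and the markers of macrophages, neutrophils, lymphocytes and endothelial cells, with medians between 0.21 and 0.68. Those lower were FXR targets (median -0.18), gluconeogenesis (-0.29), male-predominant genes (-0.64) and periportal genes (-0.41). Only the endothelial call was kept whichever array was left out, and 5 lists passed without Fxr+/+ vehicle replicate 2. The Fxr-/- vehicle array could not be left out, since its group would then be empty. All medians but that of periportal genes moved by more than 1.5 times without some array. Without Fxr+/+ vehicle replicate 1 they were -0.08 for FXR targets, 0.42 for CAR and PXR targets, 0.57 for the cell cycle, 1.02 for macrophages and 1.38 for neutrophils. Without vehicle replicate 2 they were -0.46 for gluconeogenesis, 0.38 for CAR and PXR targets, 0.26 for macrophages, 0.15 for neutrophils and 0.30 for endothelial cells. Without Fxr+/+ GW4064 replicate 1 male- and female-predominant genes and lymphocytes were at -0.27, 0.12 and 0.99, and without replicate 2 FXR targets, female-predominant genes and lymphocytes at -0.35, 0.36 and 0.21. Without Fxr-/- GW4064 replicate 1 CAR and PXR targets and male-predominant genes were at 0.54 and -0.41. Without replicate 2 CAR and PXR targets turned to -0.08 (adjusted p = 0.218), with FXR targets at -0.30, gluconeogenesis at -0.49, macrophages at 0.37 and endothelial cells at 0.20. The other 17 lists did not pass (adjusted p between 0.102 and 0.987). They were bile acid synthesis, bile acid transport, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, lipoproteins, NRF2 and glutathione, acute phase, complement, amino acid metabolism, ER stress, the clock, pericentral genes and the markers of stellate, bile duct, red blood and acinar cells.

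**Figure D2:**
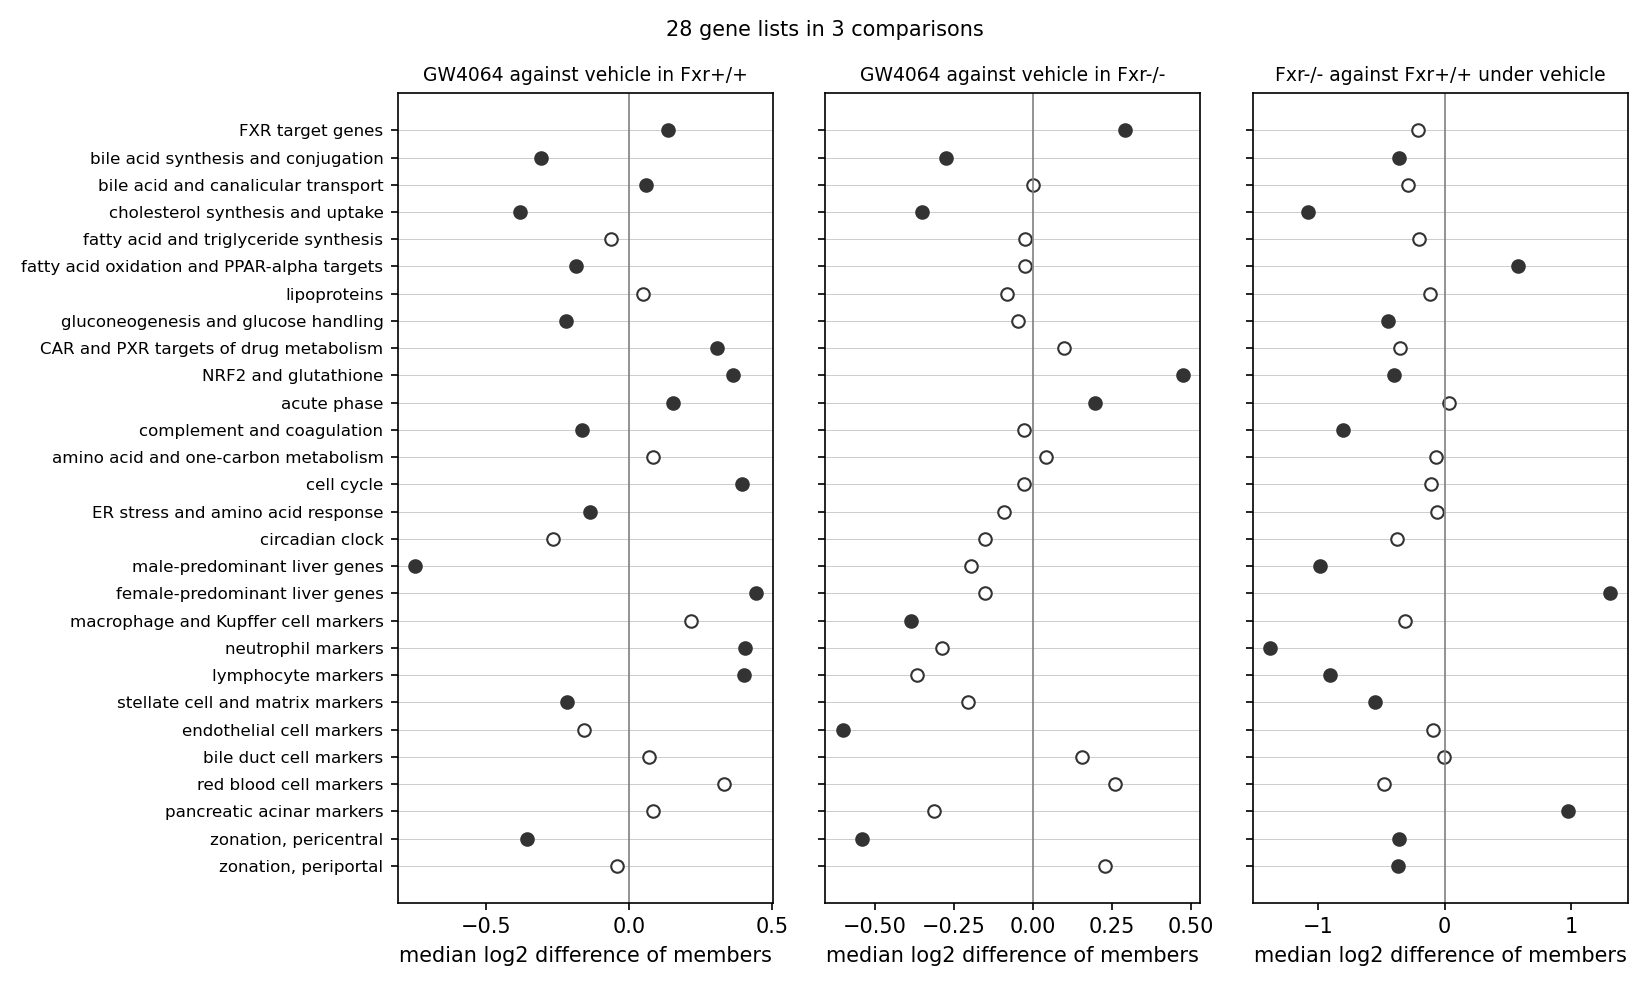
Median log2 difference of the tested members (x axis, a scale of its own in each panel) of 28 gene lists (y axis) in 3 comparisons. Filled points passed camera with the preset correlation at an adjusted p under 0.05 and open points did not. NRF2 and glutathione genes lie above 0 with GW4064 under both genotype labels (0.36 and 0.48) and below 0 in arrays labelled Fxr-/- under vehicle (-0.40).

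The genotype labels differed widely under vehicle. Relative to Fxr+/+, 181 genes were higher and 486 lower on the vehicle array labelled Fxr-/- (limma, 667 of 9766 genes), and 2370 had an unadjusted p under 0.05 against 488 expected by chance. The direction rests on 2 arrays against 1. Without any single Fxr+/+ array the count fell to between 102 and 104 higher, and leaving out Fxr+/+ vehicle replicate 1 or 2 left 311 or 298 lower.

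Fatty acid oxidation genes were higher in arrays labelled Fxr-/-. Ehhadh, the peroxisomal bifunctional enzyme, had a signal of 9219 against 710 ± 105 (SD, n = 2; log2 difference 3.68, SE 0.271, adjusted p = 0.000908), and Pdk4, which restrains pyruvate oxidation, 2679 against 121 ± 24.7 (SD, n = 2; 4.31, SE 0.365, adjusted p = 0.00108). The acyl-CoA thioesterases Acot1 (2.92, SE 0.382), Acot2 (3.55, SE 0.492) and Acot3 (2.96, SE 0.24) were higher, although Acot1 and Acot2 are near-identical paralogs and the other probe of Acot2 had the opposite sign. The list of fatty acid oxidation and PPAR-alpha targets had 18 of 22 members above 0 (median 0.58, adjusted p = 1.54e-05; 0.294 with an estimated correlation), with 6 members higher over all genes and 10 adjusted over the list alone. Other large rises were Pnliprp1, a pancreatic lipase-related protein (at least 12.4-fold), Slc13a2, a dicarboxylate transporter (at least 6.46-fold), Rcan2 (3.91, SE 0.367), and the cytochrome c oxidase subunits Cox6b2 (3.54, SE 0.575; 1.17 by its other probe) and Cox7a1 (3.37, SE 0.298). The lipoprotein receptor Vldlr rose by 3.24 (SE 0.307, adjusted p = 0.00165), the monoacylglycerol acyltransferase Mogat1 by 2.12 (SE 0.237) and cyclin D1 (Ccnd1) by 1.94 (SE 0.304).

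Complement and coagulation genes were lower, as were single genes of other hepatocyte functions. The largest falls were Haao, of the kynurenine pathway (7853 ± 3024 (SD, n = 2) against 164; -5.40, SE 0.402), Cidec, a lipid droplet protein (at least 11.2-fold), Hsd3b5, a male-predominant steroid dehydrogenase (at least 30.9-fold), Nox4 (at least 11-fold), the lysolipid transporter Mfsd2a (-4.80, SE 0.271), Nxpe2 (at least 10.6-fold), Rec8 (at least 12.6-fold) and Pdzk1 (-4.46, SE 0.377). Their adjusted p lay between 0.000336 and 0.0193. Where only a bound is given, the rank rests on the offset of 16, since the size of the fall is not known. The 2 Fxr+/+ vehicle pools differed in Hsd3b5, at 668 and 2225. In complement and coagulation 22 of 26 members were below 0 (median -0.80, adjusted p = 6.09e-07; 0.331 with an estimated correlation), with 7 lower over all genes and 12 adjusted over the list alone, among them C8g (-3.77, SE 0.321), the lectin Mbl2 (-3.78, SE 0.413) and factor XII, F12 (-2.09, SE 0.243). The lipoprotein genes Apom (-2.90, SE 0.312) and Apoa4 (-3.17, SE 0.392) were lower, although that list did not pass (adjusted p = 0.14). The urea cycle enzyme Otc was at least 10.5-fold lower, Shmt2 had a value of -3.59 (SE 0.311; -1.39 by its other probe) and the methyltransferase Gnmt -1.29 (SE 0.252). Among acute phase genes Saa2 (-1.69, SE 0.226) and Saa4 (-1.99, SE 0.342) were lower, while Fgb passed with both groups within the background range.

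Bile acid and cholesterol genes were lower under the Fxr-/- label. The amidation enzymes Baat (-3.60, SE 0.356, adjusted p = 0.00197) and Slc27a5 (-3.13, SE 0.487) fell with Cyp8b1 (-2.58, SE 0.445, adjusted p = 0.0154). The list of bile acid synthesis and conjugation had a median of -0.36 (adjusted p = 0.0321; 0.42 with an estimated correlation), with 5 members lower and 1 higher over all genes, and its call was lost without Fxr+/+ vehicle replicate 1 (median -0.17, adjusted p = 0.143; -0.56 without replicate 2). Cyp7a1 did not pass (-0.62, SE 0.30, adjusted p = 0.251). The uptake transporter Slco2b1 fell (-3.27, SE 0.29), and Abcb11 (0.19, SE 0.271), Abcb4 (0.33, SE 0.246), Slc51b (at least 1.32-fold lower, adjusted p = 0.504) and Slc10a1 (-0.62, SE 0.345) did not pass. The FXR target list did not pass either (median -0.21, adjusted p = 0.287), with 2 members higher and 3 lower over all genes. Cholesterol synthesis and uptake had 18 of 18 members below 0 (median -1.08, adjusted p = 3.12e-07; 0.294 with an estimated correlation), with 6 lower over all genes and 11 adjusted over the list alone, among them Stard4 (-1.92, SE 0.272), Msmo1 (-1.61, SE 0.241) and Idi1 (-1.71, SE 0.289). The citrate carrier Slc25a1 was lower (-1.68, SE 0.272) in a fatty acid synthesis list that did not pass. Of glucose genes Igfbp1 (at least 2.36-fold) and Pck1 (-1.36, SE 0.26) were lower, in a list with a median of -0.45 (adjusted p = 0.00753; 0.294 with an estimated correlation).

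Single genes of drug metabolism and the sex-biased lists differed as well. The xenobiotic receptor CAR, Nr1i3, had a signal of 51.9 against 1049 ± 270 (SD, n = 2; -3.95, SE 0.609, adjusted p = 0.0105). Cyp2b9 (2.15, SE 0.406) and Gadd45b (2.49, SE 0.387) were higher, Cyp3a11 (-1.49, SE 0.393, adjusted p = 0.0665) and Cyp2b10 (-0.83, SE 0.281) did not pass, and neither did the list of CAR and PXR targets (adjusted p = 0.177). NRF2 and glutathione genes had a median of -0.40 (adjusted p = 0.0102; 0.331 with an estimated correlation), with Gsta1 (-2.43, SE 0.321) and Gsta2 (-1.90, SE 0.323) lower and Gstm2 (1.69, SE 0.233) higher; these are families of similar sequence whose probes may cross-hybridise. Female-predominant genes had 10 of 10 members above 0 (median 1.31, adjusted p = 1.75e-05; 0.294 with an estimated correlation), including Cyp17a1 (2.54, SE 0.316). Male-predominant genes had 13 of 14 below 0 (median -0.98, adjusted p = 1.54e-05; 0.331 with an estimated correlation), including Cyp2f2 (-3.67, SE 0.262) and Cyp2d9 (-1.38, SE 0.25). Periportal genes, with Aldh1b1 (-1.87, SE 0.226) lower, had a median of -0.37 (adjusted p = 0.0321; 0.331 with an estimated correlation; median -0.23 without Fxr+/+ vehicle replicate 2) and pericentral genes -0.36 (adjusted p = 0.00942; 0.424 with an estimated correlation). The clock gene Ciart was lower (-1.85, SE 0.292).

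Markers of other cells moved with the label. Neutrophil markers had 10 of 10 members below 0 (median -1.38, adjusted p = 5.68e-05; 0.42 with an estimated correlation; median -0.83 without Fxr+/+ vehicle replicate 1), with Mpo at least 1.05-fold lower and Elane within the background range in both groups. Lymphocyte markers had 12 of 12 below 0 (median -0.90, adjusted p = 0.00248; 0.42 with an estimated correlation). Stellate and matrix markers had a median of -0.55 (adjusted p = 0.011; 0.501 with an estimated correlation), with Timp1 at least 1.73-fold and Col3a1 at least 1.67-fold lower; that list's call was lost without Fxr+/+ vehicle replicate 1 (0.0688). Pancreatic acinar markers had a median of 0.97 over 5 members (adjusted p = 0.00242; 0.294 with an estimated correlation), with Cela3b (1.13, SE 0.235) higher beside Pnliprp1. Alas2, a red blood cell gene (-3.09, SE 0.367), and the keratins Krt23 (-2.85, SE 0.28) and Krt8 (-1.13, SE 0.223) were lower in lists that did not pass. Aurka passed with both groups within the background range, in a cell cycle list that did not pass. Macrophage and endothelial markers, bile acid transport, amino acid metabolism, acute phase, ER stress, the clock and the lists said above to have missed the threshold had adjusted p between 0.0748 and 0.998. By fry, 12 of the 28 lists passed in this comparison, and 9 of them were among the 14 that passed camera in the same direction.

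Of the 62 genes named above that passed under vehicle, 28 kept their call in every alternative. The calls of 48 were kept whichever of 6 arrays was left out. The only Fxr-/- vehicle array, on which all these differences rest, could not be left out. The calls lost without at least 1 array were those of Cela3b, Col3a1, Cyp2b9, Cyp2d9, Cyp8b1, Elane, Fgb, Gnmt, Gsta2, Hsd3b5, Idi1, Krt8, Pck1 and Saa4.

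Under GW4064 the labels differed at 532 genes higher and 893 lower in Fxr-/-. Of the genes called in both genotype comparisons, 149 were higher and 388 lower in both, and 2 had opposite directions, where independent lists would share 9.86 and 44.4. These comparisons share no array, but they use the same estimate of each gene's spread, which can raise the overlap. Without Fxr+/+ GW4064 replicate 1 or 2 the counts were 152 and 149 higher and 429 and 349 lower, and without Fxr-/- GW4064 replicate 2 they were 152 and 458. Camera passed 13 lists, none of them with an estimated correlation (adjusted p between 0.305 and 0.397). Fry also passed 13, of which 7 were the same: fatty acid oxidation, bile acid synthesis, cholesterol synthesis, CAR and PXR targets, complement and coagulation, neutrophil and lymphocyte markers. Cell cycle, male-predominant, pericentral, macrophage and endothelial genes had 0.072 each by fry, and stellate genes 0.128. Fatty acid oxidation (median 0.85) was the list that rose. Those that fell were bile acid synthesis (-0.36), cholesterol synthesis (-0.92), CAR and PXR targets (-1.16), complement and coagulation (-0.50), the cell cycle (-0.56), male-predominant genes (-0.43), pericentral genes (-0.49) and the markers of macrophages (-0.83), neutrophils (-2.19), lymphocytes (-1.48), stellate cells (-0.51) and endothelial cells (-0.49). Without Fxr+/+ GW4064 replicate 2 the calls of male-predominant (adjusted p = 0.263) and stellate genes (0.125, median -0.09) were lost, and without Fxr-/- GW4064 replicate 2 those of stellate (0.068) and endothelial genes (0.0785, median -0.19). The other 15 lists had adjusted p between 0.0502 and 0.974. They included female-predominant genes, NRF2 and glutathione, gluconeogenesis, pancreatic acinar markers and periportal genes, which had passed under vehicle with 1 Fxr-/- array. The rest were FXR targets, bile acid transport, fatty acid synthesis, lipoproteins, acute phase, amino acid metabolism, ER stress, the clock and the markers of bile duct and red blood cells.

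**Figure D3:**
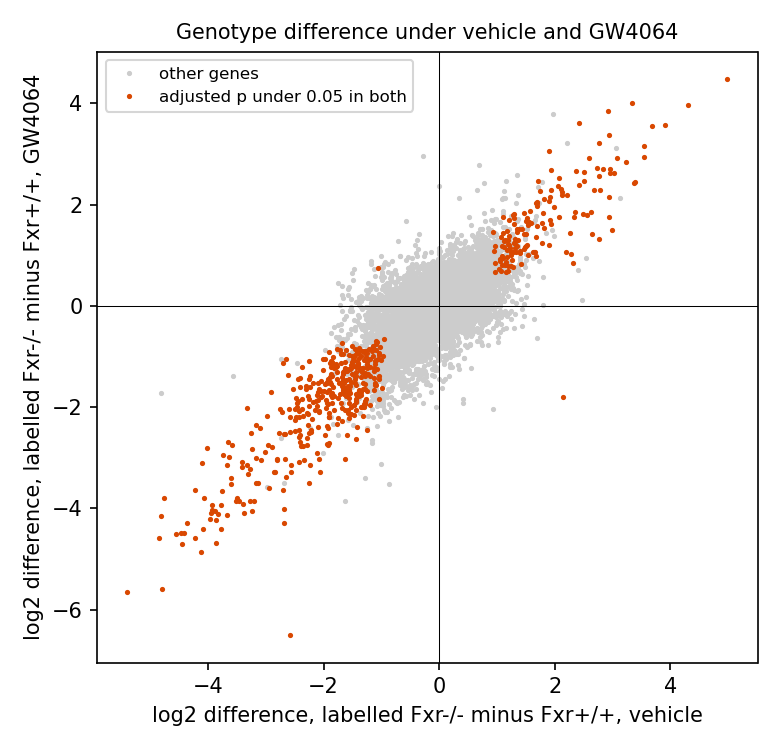
Log2 difference between the genotype labels (Fxr-/- minus Fxr+/+) under vehicle (x axis) and under GW4064 (y axis) for the 9766 genes tested, 1 point per gene. Orange points passed an adjusted p under 0.05 in both comparisons, 149 of them higher and 388 lower in both.

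The GW4064 response in Fxr+/+ and the genotype difference under vehicle share the Fxr+/+ vehicle arrays. None of the 2 genes called for GW4064 in Fxr+/+ was among the 667 called for genotype. Independent lists would share 0.137, and 100 simulations of unchanged groups shared 0.03 on average. With 2 genes called, an overlap of 0 was nearly fixed in advance. The simulated groups also held no change, unlike the data, so these values do not test a relation between the comparisons. The genotype differences of the 2 genes were 0.92 (SE 0.264, adjusted p = 0.0822) for Cyp2b13 and -0.62 (SE 0.30, adjusted p = 0.251) for Cyp7a1. The vehicle group has 2 arrays, too few to split into parts of 2.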

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

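The tests of explanations in this part were chosen after the results were seen, and the test of the difference between the labels before. The effect of GW4064 differed between the genotype labels for 11 gene lists by camera's test of the difference, though no single gene passed it and no list passed with an estimated correlation (adjusted p between 0.489 and 0.585). The medians of the difference, the effect in Fxr+/+ minus that in Fxr-/-, were -0.177 for FXR target genes, -0.288 for gluconeogenesis, 0.208 for CAR and PXR targets, 0.315 for the cell cycle, -0.635 for male-predominant genes, 0.239 for female-predominant genes, 0.634 for macrophage markers, 0.682 for neutrophil markers, 0.63 for lymphocyte markers, 0.496 for endothelial markers and -0.412 for periportal genes. With 1 array left out, the median nearest 0 was -0.0841 for FXR targets (without Fxr+/+ vehicle replicate 1). For macrophages and neutrophils it was 0.263 and 0.151 (vehicle replicate 2). For male- and female-predominant genes it was -0.266 and 0.117 (Fxr+/+ GW4064 replicate 1), and for lymphocytes 0.206 (replicate 2). Without Fxr-/- GW4064 replicate 2 that of CAR and PXR targets turned to -0.0848 and that of endothelial cells was 0.198. The median of FXR targets was 0.135 in Fxr+/+ (0.238 and 0.0334 without GW4064 replicate 1 or 2). In arrays labelled Fxr-/- it was 0.293 (0.123 without GW4064 replicate 1). Which of these 2 medians is larger depends on the arrays. The median of the difference, however, stayed between -0.346 and -0.0841 in all 10 alternatives, of which an estimated correlation and fry cannot move it. The call of FXR targets for the difference was kept in only 5 of the 10. Cyp2b9 had signals of 565 and 437 in Fxr+/+ vehicle and 2573 and 1813 in Fxr+/+ GW4064, against 2258 in the vehicle array and 839 and 443 in the GW4064 arrays labelled Fxr-/-; its difference did not pass (adjusted p = 0.305).

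Some FXR-regulated genes changed with GW4064 in arrays labelled Fxr-/-, relative to 1 vehicle array. Slc51b rose at least 23.2-fold and Cyp8b1 fell. Cyp7a1 and Abcb11 did not pass there, with log2 changes of -2.43 and 1.61. In Fxr+/+ their changes were -2.56 and 0.57, where Cyp7a1 passed and Abcb11 did not. The call of Slc51b was kept in 2 of 6 fits that left out 1 array and ended with the replicate number as a block. A swap of single arrays between the genotypes is argued against by principal component 1, on which the labels were 64.1 units apart with no array on the other label's side. A wrong genotype label for all these animals stays open, since the lowest Nr1h4 signal there was 1851.9, far above the background range, and the place of the probe in the gene is not known. An action of GW4064 without its receptor could give the same values, and these cannot be told apart for the same reason. The genotype of the animals was not otherwise checked in these data.

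The genotype labels differed at 667 genes under vehicle. Under GW4064, 5 of 6 lists of markers of other liver cells fell by camera with its preset correlation and 0 rose. None of these passed with an estimated correlation. The falls of macrophage and endothelial (0.072 each) and stellate markers (0.128) did not pass fry. Without Fxr-/- GW4064 replicate 2 the stellate and endothelial calls were also lost. Neutrophil (median -2.19) and lymphocyte markers, which fell, also passed fry (0.0378 each). These values argue only against a larger share of those cells. They cannot tell whether hepatocytes gave way to other cells such as bile duct cells, whose markers did not pass camera. A smaller share of hepatocytes therefore stays open. Under vehicle such a share cannot be told apart, since the 3 lists that fell by camera, the lowest with a median of -1.38, did not pass with an estimated correlation (0.42 to 0.501) or fry (0.104 to 0.193) and bile duct markers fell by fry (0.0338) but not by camera (0.217), and neither can a fasted state: Pck1, Igfbp1 and G6pc had a median of -1.36, but the call of Pck1 was lost without either Fxr+/+ vehicle array (highest adjusted p = 0.076), Igfbp1 in the Fxr-/- array was within the background range, G6pc did not pass (0.733) and Tat was under the filter. A lower activity of the hepatocyte regulator HNF4A may account for part of the falls: Hnf4a itself was lower (log2 difference -1.29, SE 0.226, adjusted p = 0.0167) in the single Fxr-/- vehicle array and less so under GW4064 (-0.61, SE 0.185, adjusted p = 0.0689, not past the threshold), and 26 textbook targets not named in the report had a median of -0.466 and -0.601 in the 2 comparisons, below all 10000 random lists of similar expression, with 6 and 7 lower and 0 higher past the threshold. The random lists drew genes independently, so targets that are regulated together could fall below them whatever the cause. No fixed list passed with an estimated correlation in either comparison. The median of the targets was also lower under GW4064, where Hnf4a fell less. These values do not show a lower activity of HNF4A, which remains a hypothesis. Of the targets, 21 also belong to the fixed lists. The labels give no litter, batch or array by which a technical cause could be tested.

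The column of Fxr-/- vehicle replicate 2 held values unlike a signal. The signal of a failed hybridisation is argued against as the content of the column, because 100% of the values were whole. Whether that array's hybridisation failed cannot be told from values of another kind. Another unit, such as the number of beads per probe, may be what the column holds. Its highest Spearman correlation with another array was 0.0559, which other values without a signal could also give, so the unit stays unknown. No biological explanation was tested for it.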

How the results depend on the processing

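Alternatives were fixed before the data were examined except those of the fit over both genotype labels. Counts of calls, lists and fixed results were compared with the reported ones 249 times, and 161 stayed within 1.5 times the reported value; an added quantile normalization or median centring moved no gene count by more than that. The difference of the GW4064 effect had 0 genes higher and 0 lower except without the filter (299 higher, 25 lower) and with an offset of 1 (5 lower). Without the filter many values sit at 0, which leaves genes with no spread. The log2 difference of Nr1h4 under vehicle stayed between -0.353 and -0.339 except without Fxr+/+ vehicle replicate 1 (-0.429) or 2 (-0.274), and the overlap of called genes was 0 with the fold threshold too.

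Counts are given as higher and lower. For GW4064 in Fxr+/+ (reported 1 and 1) they were 0 and 0 with an offset of 1 and with only the groups compared, 5 and 0 without the filter, 9 and 2 with trend and robust, and 0 lower with all probes. For GW4064 in Fxr-/- (5 and 2) they were 34 and 8 with an offset of 1, 48 and 331 without the filter, 2 and 1 with all probes, 1 and 1 with the mean of probes and with array weights, 12 and 4 with trend and robust, 0 and 0 with only the groups compared, and 3 higher with an offset of 100. For genotype under vehicle (181 and 486) they were 477 and 230 without the filter, 98 and 295 with only the groups compared, and 120, 354 and 337 higher with offsets of 1 and 100 and with trend and robust. For genotype under GW4064 (532 and 893) they were 157 and 225 without the filter, and 294, 802 and 306 higher with offsets of 1 and 100 and the fold threshold. Apart from the filter and the groups fitted, which change the number of genes or arrays, the cause was not tested.

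With each array left out, counts ran from 0 to 1 higher and 0 to 1 lower for GW4064 in Fxr+/+, 0 to 2 and 1 to 1 for GW4064 in Fxr-/-, 0 to 0 and 0 to 0 for the difference, 102 to 172 and 298 to 469 for genotype under vehicle, and 149 to 532 and 349 to 893 under GW4064. Lists past the threshold ran from 13 to 18, 8 to 9, 5 to 13, 12 to 16 and 11 to 16 in the same order (reported 18, 8, 11, 14 and 13), and the fit over both labels from 0 to 5 genes (reported 7). Without Fxr-/- vehicle replicate 1 that group is empty, so only comparisons without it could be fitted. With an estimated correlation 0 lists passed in all 5 comparisons, and with fry 0 passed in the 3 GW4064 comparisons.

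The replicate numbers are shared by the groups but are not known to pair samples. The only Fxr-/- vehicle array is replicate 1, so a difference between the numbers would enter its comparisons. The differences between replicates 1 and 2 correlated at 0.24, 0.377 and 0.233 between groups. With the number as a block, counts were 4 and 1 for GW4064 in Fxr+/+, 2 and 1 in Fxr-/-, 0 and 0 for the difference, 338 and 635 for genotype under vehicle and 877 and 1123 under GW4064, and 17, 7, 11, 15 and 14 lists passed. The calls of Slc51b, Etv4 and Mfap2 (adjusted p = 0.0738 each), Synm (0.0967), bile acid synthesis (0.166) and macrophage markers (0.132) in Fxr-/- and of bile acid synthesis (0.0758) and transport (0.0607) in Fxr+/+ ended, while Gstm3 in Fxr+/+ (0.0382) and Cyp3a11 for genotype under vehicle (0.0169) passed. The list medians that moved by more than 1.5 times were those of pericentral genes in Fxr-/- (-0.541 to -0.272) and, for the difference, of FXR targets (-0.177 to -0.286), CAR and PXR targets (0.208 to 0.0798), female-predominant genes (0.239 to 0.0772), neutrophil markers (0.682 to 0.376) and endothelial markers (0.496 to 0.320).

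Of 1336 comparisons of named genes past the threshold, 1170 kept the call, 166 lost it and 0 reversed. Calls kept in every alternative were 28 of 62 for genotype under vehicle, 0 of 2 for GW4064 in Fxr+/+ and 0 of 7 in Fxr-/-. The genes that reversed had not passed. Abcb4 was -0.106 and -0.0662 in Fxr+/+ without vehicle or GW4064 replicate 2 (up to 0.171 with others left out), 0.0366 and 0.0700 in Fxr-/- with the block or without GW4064 replicate 2 (down to -0.0700), and -0.00427, -0.106, -0.0662 and -0.0377 for the difference with the block or without a replicate 2 array (up to 0.171). For the difference, Cyp3a11 was 0.145 and 0.299 (down to -0.570) and Cyp7a1 0.131 and 0.0570 (down to -0.401) without Fxr+/+ vehicle or Fxr-/- GW4064 replicate 1, and Slc51a was -0.205 with an offset of 1 and -0.394 and -0.0837 without Fxr+/+ GW4064 replicate 2 or Fxr-/- GW4064 replicate 1 (up to 0.426). The median of CAR and PXR targets for the difference turned to -0.0848 without Fxr-/- GW4064 replicate 2. In Fxr+/+, 2 list calls ended with a turn of sign: neutrophil markers had a median of -0.0693 without vehicle replicate 2 (up to 0.83 otherwise), and stellate markers 0.0522 without GW4064 replicate 1 (down to -0.37 otherwise). The cause was not tested. Signal over background limits genes such as Nr0b2 and Slc51a, which no array measured above the range of the background.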

Other observations

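The average effect of GW4064 over both genotype labels was fitted after the data had been seen, with genotype label and treatment as additive terms over 4 GW4064 and 3 vehicle arrays. It passed 7 genes, 6 higher and 1 lower, all with the same sign under both labels, and 771 genes had an unadjusted p under 0.05 against 488 expected by chance. Cyp7a1 fell by 2.51 on the log2 scale (SE 0.179, adjusted p = 0.0049). Ppl, which encodes the epithelial protein periplakin (1.68, SE 0.186), and Wfdc3 (1.99, SE 0.204) were higher. So were Slc51b (adjusted p = 0.0241), Amn (0.0182) and the antioxidant genes Gstm3 (0.0323) and Gpx2 (0.0241), for which no size is given because at least 1 vehicle group lay within the background range. By camera 13 lists passed, 5 higher and 8 lower, none with an estimated correlation. NRF2 and glutathione genes (median 0.425, adjusted p = 3.82e-10; 0.176 with an estimated correlation) and acute phase genes (median 0.20; 0.176 with an estimated correlation) were higher, and cholesterol synthesis and uptake was lower (median -0.43, adjusted p = 2.33e-09; 0.176 with an estimated correlation). These 3 lists also passed fry (adjusted p = 0.0459 each). The other 10 were FXR targets (0.17), CAR and PXR targets (0.245) and the cell cycle (0.25) above 0, and bile acid synthesis (-0.16), fatty acid oxidation (-0.13), complement (-0.10), male-predominant genes (-0.46), stellate (-0.14) and endothelial markers (-0.305) and pericentral genes (-0.44) below 0.

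Chance was not excluded for this count. Of the 34 splits of the 7 arrays into 4 and 3 that could be fitted, 2 gave at least 7 genes, the real one included, and the highest other gave 9. That other split set the replicate 1 arrays against the replicate 2 arrays. With the replicate number as a block, 5 genes were higher and 1 lower, and 5 of these 6 were among the 7. Slc51b and Gstm3 no longer passed with the block. Leaving out Fxr+/+ GW4064 replicate 1 left 0 genes, leaving out Fxr+/+ vehicle replicate 1 or Fxr-/- GW4064 replicate 1 left only Cyp7a1, and the count was at most 5 without any single array.

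Sex-biased genes differed between pools of male mice, and 2 are given that were chosen after their values were seen. Hsd3b5 had signals of 668 and 2225 in Fxr+/+ vehicle, 47.3 and 251 in Fxr+/+ GW4064, and between 18.9 and 29.0 in the 3 arrays labelled Fxr-/-. Cyp2b13 had 47.9 and 44.5 in Fxr+/+ vehicle, 502 and 369 in Fxr+/+ GW4064, and between 85.2 and 102 in arrays labelled Fxr-/-.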
